A study of Danio rerio with 14 samples.

How the data were processed

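Gene expression was measured in whole zebrafish embryos with Agilent oligonucleotide arrays read in 2 channels. The 14 arrays comprised 12 that set RNA of exposed embryos, labelled with Cy5, against RNA of solvent (DMSO) control embryos, labelled with Cy3, and 2 self-to-self arrays that carried the same RNA in both channels. The 12 treated arrays fell into 4 groups of 3: b-naphthoflavone at 38.5 µg/L, benzo(a)pyrene at 33.2 µg/L and benzo(k)fluoranthene at 12.7 µg/L, all sampled at 2 days post-fertilization (dpf), and benzo(a)pyrene at 0.1 mg/L sampled at 5 dpf. Per the labels' protocols, each biological replicate was RNA of 50 embryos and 200 ng of total RNA was labelled. The labels call the control a pool of embryos in the sample sources but say in the treatment protocol that each replicate had its own DMSO control. Whether the arrays at 2 dpf shared 1 control pool is not given in the sources used here. All treated arrays had the same dye orientation, so a gene-specific dye effect does not cancel within a group.

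Per the file headers, the intensity values were median pixel signals of each spot and of its local background, written by Agilent Feature Extraction 10.5.1.1 with no normalization. Per the file headers, the same files hold processed signals, which are intensity values after background subtraction and dye normalization by that software, and a log10 ratio of the processed Cy5 over Cy3 signals. The deposited series table holds log2 ratios of Cy5 over Cy3. Its scale, centring and direction were found by setting each column against the same array's signals. Every column matched a loess fit of background-subtracted signals with 50 added, to within 0.00146 on the closest array and 0.0253 on the farthest, and the medians of the columns ran from 0.00151 to 0.00914, so none of the 3 stayed unknown.

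The main values were computed from the median foreground and median background intensities in R 4.3.3 with limma 3.58.1. The design had named the mean foreground signal, which the files do not hold, so the median foreground was used in its place. Background was corrected with normexp and an offset of 50, and each array was normalized by loess, with control spots at weight 0. Afterwards control spots and spots marked by the software as non-uniform were left out, and no scaling between arrays was applied. Of 43803 spots that were not controls, 50 probes lay on 5 spots each and were averaged, which left 43603 probes. A probe was tested where it was well above background in the same channel on all 3 arrays of at least 1 treated group, which held for 33506 probes. A gene with several tested probes was represented by its brightest probe over all arrays. Among 7968 genes with several tested probes, the highest and lowest probes differed by over 1 on the log2 scale for 63 genes in the b-naphthoflavone group, 15 for benzo(a)pyrene at 2 dpf, 34 for benzo(k)fluoranthene and 16 for benzo(a)pyrene at 5 dpf.

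Accessions of the array design were paired with current gene symbols through the reference tables of gene names, which belong to a newer assembly and were used for names alone. A symbol was found for 25069 probes, and 18534 probes stayed without one, of which 9257 carried Ensembl transcript identifiers that the tables do not hold. The 21295 genes tested were 11500 with a symbol and 9795 tested under their own accession. Genes that share probes with a close paralog, such as the crystallin, globin and apolipoprotein families, were measured with whatever cross-hybridisation the probes have.

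For each group, a linear model of the log2 ratio was fitted with limma to the 12 treated arrays, with 1 coefficient per group, 1 estimate of spread shared by all groups on 8 residual degrees of freedom, and moderated by eBayes. The group mean was tested against 0 for the comparison with DMSO, and the difference of 2 group means for the comparison between treatments. A gene was called where the Benjamini-Hochberg adjusted p over the genes tested was under 0.05. The test against 0 leaves out the control's own spread, and gene p-values rest on spread within groups, those of lists on spread between genes. Intervals are at the 95 percent level.

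Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, two-sided, adjusted over the lists within a comparison, and again with a correlation estimated from the data. A list is described as called where the adjusted p with the preset correlation was under 0.05. The 35 lists, each with at least 5 tested genes, were fixed before the data were examined, as were the main design, the rule for named genes and most alternatives. Of 1355 entries, 1328 matched a symbol (not all tested) and 27 did not. The lists cover the AhR (aryl hydrocarbon receptor) battery and the receptor with its partners; other cytochromes P450 of families 2 to 4, phase II conjugation and xenobiotic transporters; the Nrf2 oxidative stress response, DNA damage, heat shock, the unfolded protein response and hypoxia; tissues (heart muscle, skeletal muscle, lens, photoreceptors, exocrine pancreas, liver, intestine, red blood cells, immune cells, pigment cells and neural crest, cartilage and bone, connective tissue, neurons and glia, endothelium, epidermis and ionocytes); and the cell cycle, circadian clock, sterol synthesis, retinoids, glucocorticoid response, immediate early genes, thyroid axis, ribosomal proteins, mitochondrial respiration, and yolk and estrogen response. Lists of 15 yolk syncytial layer and 5 hatching gland markers were written only after the data had been seen and were used as descriptions, with 11 and 5 genes tested.

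The genes named per comparison with DMSO were the 10 highest and the 10 lowest by mean log2 ratio among called genes with a symbol and the same sign on all 3 arrays that also had the same sign, with an unadjusted p under 0.05, against the mean of the 2 self-to-self arrays. Added to them were every measured gene of the AhR battery and, for each called list, up to 4 called members with the largest change. For differences between treatments the 5 highest and 5 lowest called genes were taken where the arrays of the groups did not overlap, which chance alone gives in 10 percent of genes in a comparison of 3 arrays with 3. The values of 2 genes that the rule names are not reported here. Any other gene named, such as a called member that moved against the rest of its list, was chosen after its values were seen. Where a probe was not well above background in the control channel on any array of a group, a fold is given as a lower bound, "at least N-fold", computed from each channel's normalized log2 signal as the mean of the treated channel against the lowest signal well above background, or the probe's own signal where that was higher. Such bounds are open to dye bias, since dyes were not swapped.

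The alternatives planned beforehand were no background correction, the software's processed signals centred on the median, median centring in place of loess, Aquantile after loess, the series table, no filter and a stricter filter on dim probes (well above background in both channels on all 12 treated arrays, 23775 probes), the mean of the probes of a gene, eBayes with trend and robust options, the arrays of the compared groups alone, the contrast against the self-to-self arrays, the replicate number as a block, the slide or scan day as a block, each array left out in turn, and a threshold of 2-fold. Added after seeing the data were leaving out non-uniform spots before normexp in place of after it, leaving out b-naphthoflavone replicate 2 with benzo(k)fluoranthene replicate 3, and the treated channel alone for differences at 2 dpf. The normexp step was tested with and without the non-uniform spots because 5 spots of b-naphthoflavone replicate 2 had a very high local background. On that array the SD of the log2 ratios was 0.238 with them and 0.363 without.

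Slides and scan days were taken from the files and numbered. Slides 1, 2 and 3 each held 1 b-naphthoflavone array, slide 4 held replicates 1 and 2 of benzo(a)pyrene at 2 dpf and of benzo(k)fluoranthene, slide 5 held their replicates 3 with the self-to-self array of 2 dpf, and slide 6 held the benzo(a)pyrene arrays of 5 dpf with the other self-to-self array. Scan day 1 held b-naphthoflavone replicate 1, day 2 its replicate 2 with slide 4, day 3 its replicate 3 with slide 5, and day 4 slide 6.

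The fit and the calls were tested on simulated data of 20975 genes, drawn with the spread of the real arrays, of which 200 were changed by a known fold. At 1.5-fold the fit recovered 85.1 percent of changed genes for b-naphthoflavone, 82.1 for benzo(a)pyrene at 2 dpf, 77.6 for benzo(k)fluoranthene and 88.1 for benzo(a)pyrene at 5 dpf. At 2-fold the corresponding shares were 94.0, 92.5, 97.0 and 97.0 percent, and at 4-fold each was 100 percent. For the differences, 1.5-fold changes were recovered in 47.8 percent of genes for b-naphthoflavone against benzo(a)pyrene, 35.8 for benzo(k)fluoranthene against benzo(a)pyrene, 49.3 for b-naphthoflavone against benzo(k)fluoranthene and 50.8 for benzo(a)pyrene at 5 against 2 dpf, and 2-fold changes in 92.5, 86.6, 86.6 and 88.1 percent. Between 4 and 13 unchanged genes were called per comparison, a count that leaves out false calls from the sources not simulated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.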

Results

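Transcript levels were measured in zebrafish embryos exposed to compounds that bind the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, against embryos held in the solvent DMSO. The 12 treated arrays formed 4 groups of 3: b-naphthoflavone at 38.5 µg/L, benzo(a)pyrene at 33.2 µg/L and benzo(k)fluoranthene at 12.7 µg/L at 2 days post-fertilization (dpf), and benzo(a)pyrene at 0.1 mg/L at 5 dpf. Another 2 arrays were self-to-self, carrying 1 RNA in both channels: solvent control RNA labelled as that of the b-naphthoflavone experiment at 2 dpf, and RNA of benzo(a)pyrene embryos at 5 dpf. Between 64.4 and 80.2 percent of spots were well above background in the treated channel, and between 58.4 and 83.2 percent in the control channel, with no saturated spot. Values are log2 ratios of the treated over the DMSO channel, and the number of arrays limits their precision. The median standard error (SE) of a gene was 0.089 against DMSO and 0.126 for a difference between treatments. A test of the ratio against 0 leaves out the control's own spread, and gene p-values measure the spread between arrays within groups.

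Embryos at 2 dpf were compared with DMSO to find the genes that respond to b-naphthoflavone, a synthetic flavone. cyp1a, the monooxygenase gene most used as a marker of AhR activation, rose by 5.30 on the log2 scale (SE 0.291, n = 3, 39.3-fold, adjusted p = 4.09e-06), on 3 of 3 arrays. Its relatives cyp1c1 and cyp1b1 rose 2.93-fold and 2.31-fold, the AhR repressor ahrra 2.36-fold, the glutathione transferase gstp1.2 2.88-fold and the sulfotransferase sult6b1 2.38-fold, with SEs from 0.159 to 0.202 on the log2 scale. Among genes outside the AhR battery, desi1a, which encodes a peptidase that removes SUMO tags, rose 3.7-fold (log2 1.89, SE 0.132) and the kinase gene mapk3 2.21-fold. Among the deepest falls were lipid carriers of yolk and liver. apoa2 was 6.06-fold lower (log2 -2.60, SE 0.664, adjusted p = 0.0339), apobb.1 4.52-fold, apoeb 3.54-fold and the glutathione peroxidase gpx4a 3.81-fold. The control channel of these 4 was higher than under the other 2 compounds by 2.02, 1.62, 1.33 and 1.29, and may carry part of the falls.

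Of 15 AhR battery genes tested, 8 rose under b-naphthoflavone, 0 fell and 7 were not called, and 9 were called when adjusted over the list alone (list adjusted p = 2.59e-07, adjusted p = 0.497 with an estimated correlation). The 8 included cyp1c2 (0.98) and sox9b, a cartilage regulator (0.38). None of the 12 called lists of b-naphthoflavone held: the immediate early list gave an adjusted p = 0.497 with an estimated correlation, as the AhR battery did, and the other 10, given here and in the next paragraph, an adjusted p = 0.671 with an estimated correlation. Photoreceptor genes had 9 of 44 called lower and 0 higher, 15 adjusted over the list alone (adjusted p = 2.33e-06, adjusted p = 0.671 with an estimated correlation), with medians of -0.598, -0.00181 and -0.22 on the arrays, among them the opsin opn1lw2 (-0.96) and the transducin subunit gnb3a (-1.13). In the lens list 7 of 40 fell, 12 adjusted over the list alone (adjusted p = 1.19e-06), such as crygm5 (-0.76). Among epidermis and ionocyte genes 7 of 39 fell, 14 adjusted over the list alone (adjusted p = 6.36e-05), such as the keratins krt17 (-0.95) and krt15 (-0.93). Liver genes fell in 12 of 40, 15 adjusted over the list alone (adjusted p = 0.000583). The intestine genes fabp1b.1, rbp2b and apoa4a fell of 33, 6 adjusted over the list alone (adjusted p = 0.00887). A yolk-side set, defined below, holds 16 of the liver and 6 of the intestine genes. The immediate early list, genes of the fast response to stimulation, had 12 of 25 lower, such as fosab (-1.02) and npas4a (-0.74). maff (0.36) was higher, and 17 were called adjusted over the list alone (adjusted p = 0.00065). Mitochondrial respiration had 5 of 48 lower, such as ndufb8 (-0.43). Another 2, ndufs5 (0.25) and sdhb (0.37), were higher, with 12 adjusted over the list alone (adjusted p = 0.00533). The connective tissue genes lum (-0.72) and postnb (-0.66) fell of 21, 4 adjusted over the list alone (adjusted p = 0.00944). Of 13 yolk and estrogen genes, apoeb and the protease ctsba (-0.85) fell, 2 adjusted over the list alone (adjusted p = 0.0285).

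Ribosomal protein genes rose under b-naphthoflavone in 10 of 72, 15 adjusted over the list alone (adjusted p = 2.24e-10), with rpl24 at 0.73. Their medians were 0.268, 0.255 and 0.199 on the arrays, against 0.0696 and 0.24 on the self-to-self arrays of 2 and 5 dpf. In the Nrf2 oxidative stress list the peroxiredoxins prdx1 (0.78) and prdx6 (0.78) and the sensor keap1b (0.83, with a self-to-self mean of 0.53) were among 4 of 29 that rose. In it gpx4a, gpx4b (-0.29) and the catalase cat (-0.46) fell, 11 adjusted over the list alone (adjusted p = 0.025), with list medians of 0.113, 7.64e-05 and 0.144. Mitochondrial respiration was also not called with median centring (adjusted p = 0.559), nor the Nrf2 list with the software's processed signals (adjusted p = 0.0791). Not called were the AhR receptor and its partners (adjusted p = 0.11), where ahr2 (0.41) and hsp90ab1 (0.45) rose, DNA damage (adjusted p = 0.137), where 6 of 31 genes fell, and skeletal muscle (adjusted p = 0.159). Phase II conjugation (adjusted p = 0.203), the unfolded protein response (adjusted p = 0.357), hypoxia (adjusted p = 0.96) and heat shock (adjusted p = 0.978, median 0.0775, mean -0.0166) were not called either.

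With limma, 1579 of 21295 genes were called against DMSO for b-naphthoflavone, 712 higher and 867 lower, and 91 of them changed at least 2-fold, 31 higher and 60 lower. cyp1a was called in 18 of 18 alternatives, cyp1c1 and ahrra in 16 and cyp1b1 in 15. The count was 99 with median centring, 29 against the mean of the self-to-self arrays and 6 with only the arrays of the group. It was 462 without replicate 1, and 3195 where spots marked as non-uniform were left out before background correction, a choice that acts on replicate 2. With the software's processed signals 61.6 percent of the calls were higher, against 45.1 percent. Replicate 2 had the lowest ratios of called AhR battery genes, such as cyp1c1 (0.64 against 1.88 and 2.14). It correlated at -0.38 across genes, which are not independent replicates, with benzo(a)pyrene replicate 1.

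The comparison of benzo(a)pyrene, a polycyclic aromatic hydrocarbon, with DMSO at 2 dpf asked which genes respond to it at 33.2 µg/L. cyp1a rose 9.69-fold (log2 3.28, SE 0.291, n = 3, adjusted p = 0.00152) on 3 of 3 arrays, and sult6b1 rose 1.78-fold (log2 0.83, SE 0.159, adjusted p = 0.027). The hatching enzyme genes he1.1 and he1.2, whose proteases dissolve the egg envelope, rose 4.06-fold and 2.86-fold, with SEs of 0.408 and 0.341, and zgc:174855 4.16-fold (SE 0.28). The control channel of he1.1 and he1.2 was lower here (8.79 to 8.93 and 11.1 to 11.5) than on the b-naphthoflavone arrays, where it was at least 10.3 and 12.4. The acid phosphatase acp5a, the methionine enzyme mat1a, the amino acid oxidase dao.1 and the fatty acid carrier fabp2 rose between 2.62-fold and 3.29-fold. The clock gene per1b was the lowest at -0.86 (SE 0.133, 1.81-fold lower, adjusted p = 0.01), followed by the transcription factor gene mafba (-0.63).

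Only cyp1a and sult6b1 were called of the 15 AhR battery genes under benzo(a)pyrene at 2 dpf, 2 adjusted over the list alone (list adjusted p = 0.00599, adjusted p = 0.504 with an estimated correlation, and adjusted p = 0.133 with median centring). Values that did not pass were 0.49 for cyp1c1 (adjusted p = 0.225), 0.41 for ahrra (adjusted p = 0.288), 0.28 for cyp1c2 (adjusted p = 0.393) and 4.48e-05 for cyp1b1 (adjusted p = 1). Tissue lists shifted upward through many small ratios: liver had 3 of 40 called, ambp (2.46-fold), leg1.1 (1.96-fold) and cp (1.6-fold), and 24 adjusted over the list alone (median 0.56, adjusted p = 8.1e-12). The epidermis list followed with cyt1 (0.40) of 39 and 11 adjusted over the list alone (adjusted p = 1.68e-07). Lens had crygm2d4 (0.85) and crygm2d12 (0.79, with a self-to-self mean of 0.41) of 40 and 12 adjusted over the list alone (adjusted p = 2.1e-06), and heart muscle had gata6 (0.81) and tnnt2a (0.60) of 19 and 9 adjusted over the list alone (adjusted p = 2.62e-06). Of 24 red blood cell genes 0 were called and 11 adjusted over the list alone (adjusted p = 1e-05). Of 33 intestine genes only fabp2 was, with 12 adjusted over the list alone (adjusted p = 0.000116). Upward shifts were also called for connective tissue (0 of 21, 3 adjusted over the list alone, adjusted p = 0.000265) and phase II conjugation (0 of 46 by either adjustment, adjusted p = 0.000808, with medians of 0.272, -0.0187 and 0.26 on the arrays). The same held for other cytochromes P450 (0 of 29, 5 adjusted over the list alone, adjusted p = 0.00691), endothelium (fli1rs of 20, 4 adjusted over the list alone, adjusted p = 0.00924) and xenobiotic transporters (0 of 13, adjusted p = 0.0164). The liver and intestine lists share genes with the yolk-side set, so the control may carry part of their shifts. All of these tissue and enzyme lists, from liver to transporters, gave an adjusted p = 0.504 with an estimated correlation. cyp1a was called in 17 of 18 alternatives, with an adjusted p = 0.0978 in the other, and sult6b1 in 12 of 18.

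In the circadian list per1b, cry5 (-0.57), tefa (-0.55) and nr1d2b (-0.50) fell of 29 and nfil3-5 (0.51, with a self-to-self mean of 0.47) was higher under benzo(a)pyrene at 2 dpf, 8 adjusted over the list alone (adjusted p = 0.000265, adjusted p = 0.266 with an estimated correlation). Neurons and glia (0 of 52, median -0.104, adjusted p = 0.000282) and heat shock (0 of 21, median -0.112, adjusted p = 0.016) shifted downward, each with an adjusted p = 0.504 with an estimated correlation. Ribosomal proteins had 3 of 72 higher, 5 adjusted over the list alone (adjusted p = 0.00748, adjusted p = 0.735 with an estimated correlation): rpl8, rps18 and rpl18, with self-to-self means of 0.43, 0.60 and 0.42. Mitochondrial respiration shifted upward by 0.112 with cs (-0.38) lower of 48, 5 adjusted over the list alone (adjusted p = 0.00591, adjusted p = 0.573 with an estimated correlation). The Nrf2 list shifted by 0.17 with 0 of 29, 5 adjusted over the list alone (adjusted p = 0.016, adjusted p = 0.583 with an estimated correlation). Median centring in place of loess moved the median of all genes to 0.234 for benzo(a)pyrene at 2 dpf and to 0.28 for benzo(k)fluoranthene. Relative to that shift the benzo(a)pyrene medians turned for neurons and glia (0.0929) and heat shock (0.0697), which then lay above other genes. They also turned for the intestine (-0.186), other cytochromes P450 (-0.232) and transporters (-0.291), which lay below them. With it the adjusted p of the liver list was 0.0787, that of the endothelium 0.0905 and that of phase II conjugation 0.421, and the direction of qki2, cs, dicer1 and mybphb turned, although qki2 and dicer1 still lay below the median of all genes. Of the lists not called, the AhR receptor and its partners had a median of -0.0393 but were tested as higher (adjusted p = 0.914), and the cell cycle had a median of 0.00357 but was tested as lower (adjusted p = 0.781).

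With limma, 344 genes were called for benzo(a)pyrene at 2 dpf, 294 higher and 50 lower, and 19 of them, all higher, changed at least 2-fold. The calls rested on having 3 arrays, with 1, 2 and 1 called where replicate 1, 2 or 3 was left out, and 2 called with trend and robust options. With median centring 70.5 percent of 6640 calls were higher, against 85.5 percent. Against the mean of the self-to-self arrays limma called 0 genes, and 138 of the 344 kept their sign at an unadjusted p under 0.05.

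Benzo(k)fluoranthene, an isomer of benzo(a)pyrene with a cyclopenta ring, was compared with DMSO at 2 dpf and 12.7 µg/L to find its responding genes. cyp1a rose 253-fold (log2 7.98, SE 0.291, n = 3, adjusted p = 3.79e-08) on 3 of 3 arrays. Its relatives cyp1c1, cyp1c2 and cyp1b1, but not cyp1d1, rose 15.9-fold, 6.59-fold and 6.29-fold, ahrra 11.6-fold and sult6b1 4.61-fold, with SEs from 0.159 to 0.202. The electron donor of microsomal oxidases cyb5a rose 4.97-fold (log2 2.31, SE 0.24). The adipocyte-type fatty acid carrier fabp4b (-0.90, SE 0.191), the visual cycle enzyme rpe65a (-0.89), the keratin krt15 (-0.82) and per1b (-0.78) were the lowest.

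Of the 15 AhR battery genes 10 rose under benzo(k)fluoranthene, 0 fell and 5 were not called, with 10 adjusted over the list alone (list adjusted p = 1.15e-13, adjusted p = 0.192 with an estimated correlation). They included the transcription factor foxq1b (0.99), the ADP-ribose transferase tiparp (0.86), gstp1.2 (0.82, adjusted p = 0.0308) and ahrrb, which was at least 1.46-fold higher because its probe was not above background in the control channel. Such a bound is open to dye bias, since dyes were not swapped. Phase II genes rose in 4 of 46, 6 adjusted over the list alone (adjusted p = 0.00456, adjusted p = 0.631 with an estimated correlation), such as the glucuronosyltransferase ugt1b5 (2.78-fold), with ugt5d1 at least 1.21-fold higher (self-to-self mean 0.29). Other cytochromes P450 had 3 of 29 higher, cyp2aa8 (1.00), cyp2aa9 (0.93) and cyp2aa4 (0.69), 7 adjusted over the list alone (adjusted p = 0.025, adjusted p = 0.588 with an estimated correlation). In the Nrf2 list hmox1a (2.17-fold), tktb (0.70) and taldo1 (0.38) rose of 29, 8 adjusted over the list alone (adjusted p = 0.025, adjusted p = 0.641 with an estimated correlation). Immune genes rose in 5 of 40 and 5 adjusted over the list alone (adjusted p = 0.0454, adjusted p = 0.626 with an estimated correlation), such as cebpb (0.70) and mmp9 (0.48), with tnfb at least 1.22-fold higher, a direction that turned with median centring (-0.027).

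Liver genes rose in 11 of 40 under benzo(k)fluoranthene, 28 adjusted over the list alone (adjusted p = 3.19e-09). Among them were the complement genes cfh (3.19-fold) and c3a.3 (2.63-fold), both of the yolk-side set. Ribosomal proteins rose in 16 of 72, 25 adjusted over the list alone (adjusted p = 4.58e-09), such as rps14 (0.95, with a self-to-self mean of 0.70), with medians of 0.0987, 0.0394 and 0.621 that rest on replicate 3. Red blood cell genes rose in 5 of 24, 12 adjusted over the list alone (adjusted p = 0.000156), such as hbbe3 (1.07). Heart muscle genes rose in 4 of 19, 10 adjusted over the list alone (adjusted p = 0.000229), such as myh7l (0.87). The endothelial genes fli1rs (0.50), etsrp (0.41) and tek (0.37) rose of 20, 6 adjusted over the list alone (adjusted p = 0.0266). Lower were neurons and glia with 7 of 52, 13 adjusted over the list alone (adjusted p = 2.63e-07), such as the neuronal enolase eno2 (-0.50, with a self-to-self mean of -0.32), which turned to 0.11 with median centring. Photoreceptor genes fell in 5 of 44, 7 adjusted over the list alone (adjusted p = 7.34e-05), such as rcvrna (-0.76), while pde6ha (0.62) rose. These 7 lists each gave an adjusted p = 0.588 with an estimated correlation.

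The intestine genes fabp2 (1.52) and tm4sf4 (0.97) rose of 33 under benzo(k)fluoranthene, 3 adjusted over the list alone (adjusted p = 0.00289, adjusted p = 0.626 with an estimated correlation). Of 43 cell cycle genes rpa1 (0.40) rose, 1 adjusted over the list alone (adjusted p = 0.00306, adjusted p = 0.667 with an estimated correlation). The chaperones hsp70.3 (-0.73), hsp90aa1.2 (-0.65), hsp70l (-0.58) and dnaja1 (-0.50) fell of 21 heat shock genes, 5 adjusted over the list alone (adjusted p = 0.00184, adjusted p = 0.324 with an estimated correlation). In the circadian list 6 of 29 fell, such as tefa (-0.65) and cry5 (-0.59), and nfil3-5 (0.44, with a self-to-self mean of 0.47) was higher, 11 adjusted over the list alone (adjusted p = 0.00119, adjusted p = 0.223 with an estimated correlation). Relative to the shift of all genes under median centring, heat shock (0.068) and neurons and glia (0.00369) turned to above other genes and the intestine (-0.418) and other cytochromes P450 (-0.253) to below them. With median centring the liver (adjusted p = 0.183), heart (adjusted p = 0.0677), endothelium (adjusted p = 0.0808), phase II (adjusted p = 0.63) and immune (adjusted p = 0.903) lists were not called. With the processed signals the intestine list was not called (adjusted p = 0.12). Connective tissue (adjusted p = 0.0593), the glucocorticoid response (adjusted p = 0.297), the retinoid list (adjusted p = 0.28) and cartilage and bone (adjusted p = 0.446) were not called.

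With limma, 1513 genes were called for benzo(k)fluoranthene, 995 higher and 518 lower, and 70 changed at least 2-fold, 68 higher and 2 lower. The count was 8 against the mean of the self-to-self arrays, 11 with only the arrays of the group and 11605 with median centring. Without replicate 3 the count was 3141, and it was 262 without replicate 1 and 239 without replicate 2. Replicates 1 and 2 correlated at 0.764 across genes, against 0.18 and 0.215 with replicate 3, where acp5a was 0.31 against 2.45 and 2.87. The liver, heart and red blood cell values above rest on replicates 1 and 2, and so do the intestine (medians of 0.224, 0.337 and -0.0348), phase II (0.245, 0.374 and -0.0473) and Nrf2 (0.254, 0.215 and -0.0104) lists. The ribosomal, cell cycle (-0.0604, 0.108 and 0.303) and heat shock (-0.14, -0.0637 and -0.357) lists lean on replicate 3, where the immune list (0.156, 0.122 and 0.0114) was near 0. With the processed signals 78 percent of the calls were higher, against 65.8 percent.

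Larvae at 5 dpf exposed to benzo(a)pyrene at 0.1 mg/L were compared with DMSO to find the response at the later stage. cyp1a rose 70.7-fold (log2 6.14, SE 0.291, n = 3, adjusted p = 1.31e-07) on 3 of 3 arrays, ahrra 22.7-fold (SE 0.199), cyp1b1 19.1-fold, cyp1c1 15.6-fold and cyp1c2 5.72-fold. The skin chemokine ccl27a rose 7.06-fold (log2 2.82, SE 0.182), the heme-binding gene hebp2 5.81-fold, and the cytokine signalling repressors socs1a and socs3a 5.1-fold and 4.95-fold, with SEs of 0.0782 and 0.082. The iron hormone hamp was 3.66-fold lower (log2 -1.87, SE 0.15), fabp4b 2.9-fold and the heme oxygenase hmox1a 1.97-fold.

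In the AhR battery 10 of 15 rose under benzo(a)pyrene at 5 dpf, 1, sox9b (-0.68), fell and 4 were not called, with 11 adjusted over the list alone (list adjusted p = 1.29e-10, adjusted p = 0.0913 with an estimated correlation). Exocrine pancreas rose in 23 of 25 by either adjustment (adjusted p = 7.68e-21, adjusted p = 0.0954 with an estimated correlation), with the amylase amy2al2 2.96-fold and the elastase cela1.3 2.82-fold higher, although replicate 3 had only 0.67 and 0.37 for these. Immediate early genes rose in 14 of 25, 19 adjusted over the list alone (adjusted p = 3.42e-10, adjusted p = 0.0307 with an estimated correlation), such as klf2a (4.28-fold), atf3 (2.31-fold) and nr4a1 (2.2-fold). Glucocorticoid response genes rose in 7 of 20, 9 adjusted over the list alone (adjusted p = 1.41e-05, adjusted p = 0.0307 with an estimated correlation), led by the cochaperone fkbp5 (3.25-fold) and klf9 (3.14-fold). Immune genes rose in 16 of 40, 20 adjusted over the list alone (adjusted p = 3.61e-09), such as the NF-kB inhibitor nfkbiab (2.5-fold) and tnfb (2.25-fold). Of DNA damage genes 11 of 31 rose, 16 adjusted over the list alone (adjusted p = 1.9e-06), such as gadd45ab (2.35-fold) and the repair gene xpc (1.79-fold). Both gave an adjusted p = 0.0913 with an estimated correlation, as did pigment cells, where 5 of 24 fell, 8 adjusted over the list alone (adjusted p = 0.00449), such as the melanosome gene pmelb (-0.77).

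Photoreceptor genes fell in 24 of 44 under benzo(a)pyrene at 5 dpf, 35 adjusted over the list alone (adjusted p = 2.91e-14, adjusted p = 0.164 with an estimated correlation), such as the opsins opn1mw1 (-0.77) and opn1sw1 (-0.77), while opn1mw3 (0.37) and guca1c (0.42) rose. Cell cycle genes fell in 18 of 43, 22 adjusted over the list alone (adjusted p = 3.42e-10, adjusted p = 0.44 with an estimated correlation), such as the replication helicase mcm4 (-0.56), with tk1 (0.39) higher. Neurons and glia had 6 of 52 lower, 6 adjusted over the list alone (adjusted p = 6.71e-05, adjusted p = 0.489 with an estimated correlation), such as fabp7a (-0.72), with medians of -0.236, -0.22 and -0.013 on the arrays. Of 26 sterol synthesis genes hmgcra (-0.59), hmgcs1 (-0.41) and mvda (-0.39) fell, 5 adjusted over the list alone (adjusted p = 0.0086, adjusted p = 0.551 with an estimated correlation), with medians of -0.0794, -0.0665 and -0.328. In the Nrf2 list 13 of 29 rose, such as prdx1 (1.9-fold) and gsr (1.83-fold), and hmox1a fell, 18 adjusted over the list alone (adjusted p = 1.1e-05, adjusted p = 0.344 with an estimated correlation). The circadian list had 8 of 29 higher, such as cry5 (2.4-fold), and dbpa (-0.41) lower, 9 adjusted over the list alone (adjusted p = 0.0121, adjusted p = 0.164 with an estimated correlation). Phase II genes rose in 10 of 46, such as tpmt.1 (2.25-fold), with gstt2 (-0.33) lower, 12 adjusted over the list alone (adjusted p = 0.00449, adjusted p = 0.586 with an estimated correlation), and the shift rests on replicates 1 and 2 (medians of 0.219, 0.319 and -0.0197). Transporter genes rose in 5 of 13, such as abcg2a (2.75-fold), 6 adjusted over the list alone (adjusted p = 0.0229, adjusted p = 0.44 with an estimated correlation).

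Ribosomal proteins rose in 14 of 72 under benzo(a)pyrene at 5 dpf, 27 adjusted over the list alone (adjusted p = 7.4e-08, adjusted p = 0.509 with an estimated correlation), with medians of 0.31, 0.196 and 0.286 against 0.24 on the self-to-self array of that stage. Red blood cell genes rose in 10 of 24, 12 adjusted over the list alone (adjusted p = 2.97e-05, adjusted p = 0.44 with an estimated correlation), such as tspo (2.66-fold). Liver genes rose in 8 of 40, such as tat (1.08) and pah (1.05), against hamp, 9 adjusted over the list alone (adjusted p = 0.0154, adjusted p = 0.742 with an estimated correlation). Epidermis genes rose in 9 of 39, such as icn2 (0.79), against krt4 (-0.61), krt15 (-0.67) and cyt1 (-0.31), 12 adjusted over the list alone (adjusted p = 0.0235, adjusted p = 0.742 with an estimated correlation), and the list's shift was absent on replicate 3 (medians of 0.336, 0.362 and -0.0436). With the processed signals the liver (adjusted p = 0.0569) and transporter (adjusted p = 0.0845) lists were not called. The median and mean of lists that were not called had opposite signs for the thyroid axis (-0.0946 and 0.0834, adjusted p = 0.899), the unfolded protein response (-0.0776 and 0.00487, adjusted p = 0.398) and heart muscle (-0.029 and 0.00283, adjusted p = 0.884). Hypoxia (median 0.00804, mean 0.0776, adjusted p = 0.904) and mitochondrial respiration (median 0.00262, mean 0.0146, adjusted p = 0.661) were tested as lower.

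With limma, 3084 genes were called for benzo(a)pyrene at 5 dpf, 2162 higher and 922 lower, and 169 changed at least 2-fold, 163 higher and 6 lower. The count was 470 against the mean of the self-to-self arrays, 968 without replicate 1 and 1682 without replicate 2. With median centring 92.4 percent of 564 calls were higher, against 2162 of 3084.

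**Figure D1:**
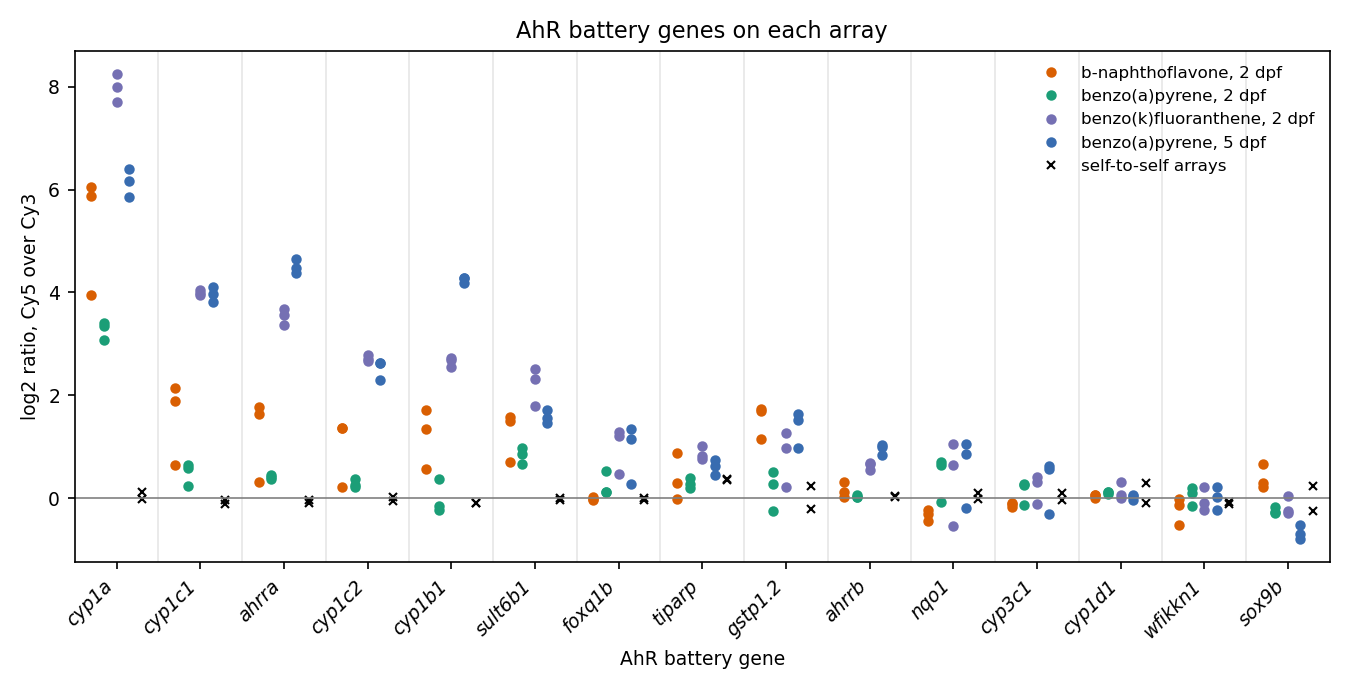
Log2 ratio of treated over DMSO for the 15 AhR battery genes, with 1 point per array, a colour per treated group and crosses for the 2 self-to-self arrays. cyp1a lies highest in each group, with means of 5.30, 3.28, 7.98 and 6.14 for b-naphthoflavone, benzo(a)pyrene at 2 dpf, benzo(k)fluoranthene and benzo(a)pyrene at 5 dpf.

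**Figure D2:**
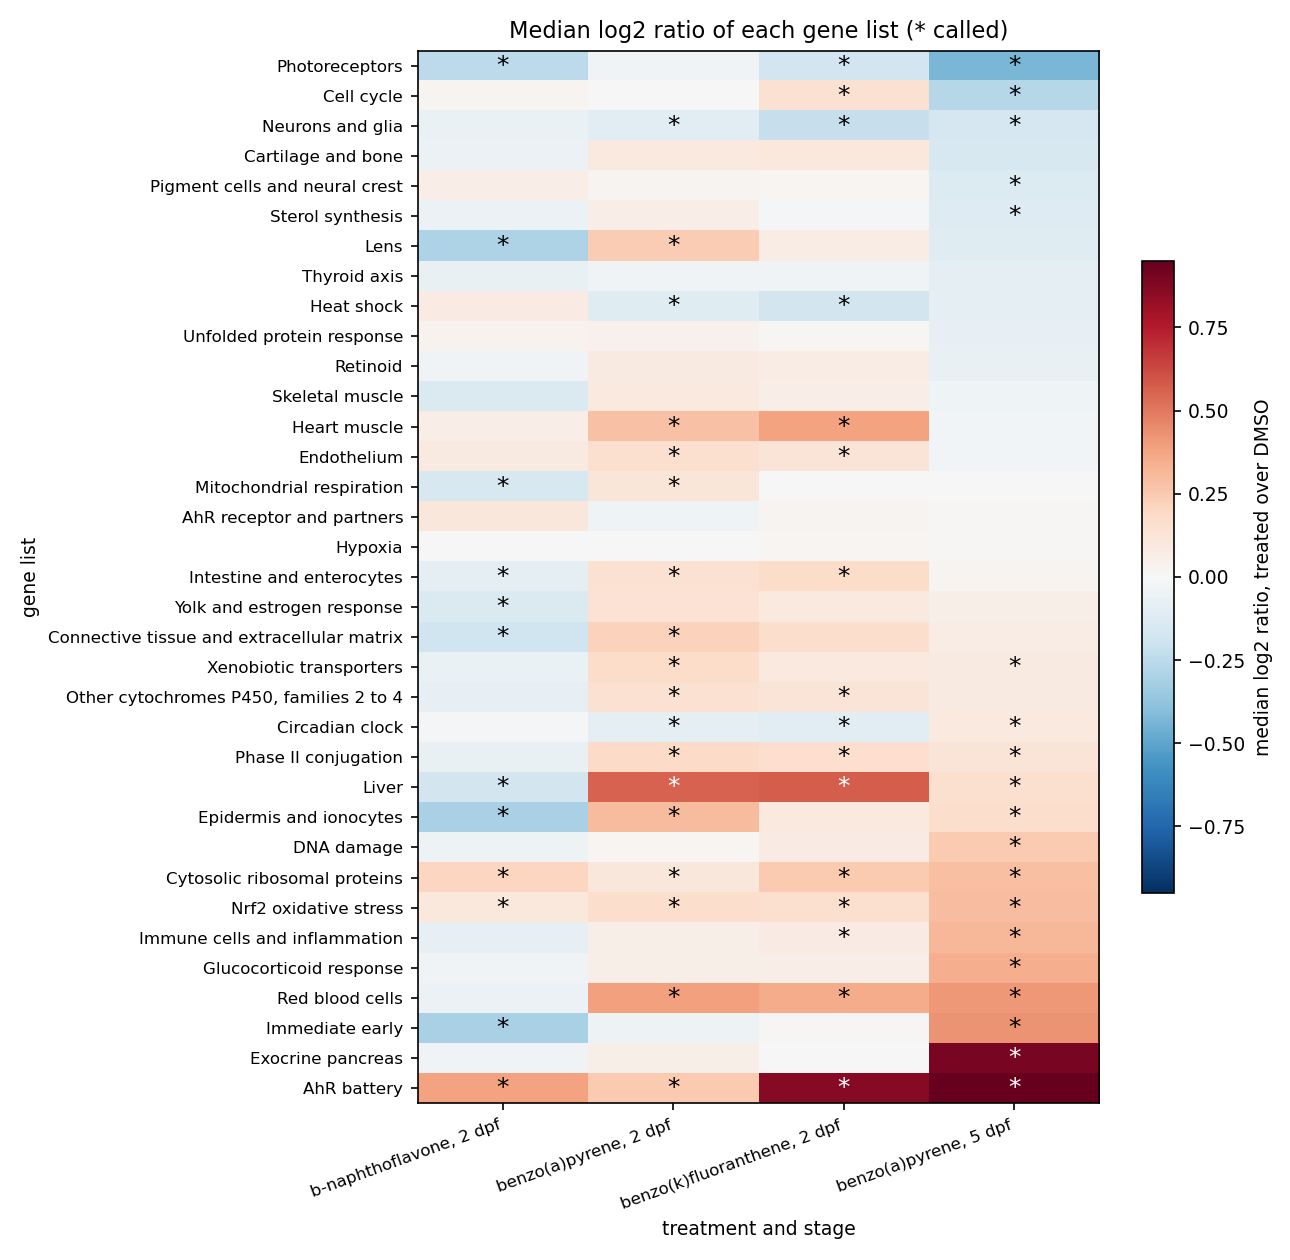
Median log2 ratio against DMSO of each of the 35 gene lists (vertical) in the 4 treated groups (horizontal), as colour, with an asterisk where camera called the list with the preset correlation. Exocrine pancreas under benzo(a)pyrene at 5 dpf has a median of 0.902, and with median centring neurons and glia, heat shock, intestine, other cytochromes P450 and transporters turn, relative to all genes, in at least 1 group of 2 dpf.

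Genes called in several groups were counted to ask what the 4 exposures share. In all 4 groups 117 genes were called higher and 0 lower, and 113 of the 117 had a mean over 0.2 on the self-to-self arrays, as 4.56 percent of all genes did. Their median was 0.608 on the self-to-self arrays and 0.595 in the treated groups, and only cyp1a and sult6b1 of the 117 had a self-to-self mean under 0.1. Across genes, which are not independent replicates, the mean ratios of benzo(a)pyrene at 2 dpf and benzo(k)fluoranthene correlated at 0.792 with a covariance of 0.0395. The 0.502 and 0.0143 simulated for unchanged groups sharing 1 control pool assumed the pool's error and decide nothing. These groups shared 237 higher genes against 13.7 for independent lists, 39 lower against 1.22, with 0 opposite. Benzo(a)pyrene at 2 and 5 dpf shared 196 higher genes against 29.8, 20 lower against 2.16, and correlated at 0.421 (covariance 0.0226). Benzo(k)fluoranthene and benzo(a)pyrene at 5 dpf shared 477 higher genes against 101, 102 lower against 22.4, and had a correlation of 0.463 and a covariance of 0.0298. b-Naphthoflavone correlated at -0.164 with benzo(a)pyrene at 2 dpf (covariance -0.00793) and at 0.00664 with benzo(k)fluoranthene (covariance 0.000387), with 132 higher in both against 9.83 and 205 against 33.3. Each of these counts of genes higher in both includes the 117 above. The covariance of benzo(k)fluoranthene with the self-to-self array of 2 dpf was 0.0203.

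**Figure D3:**
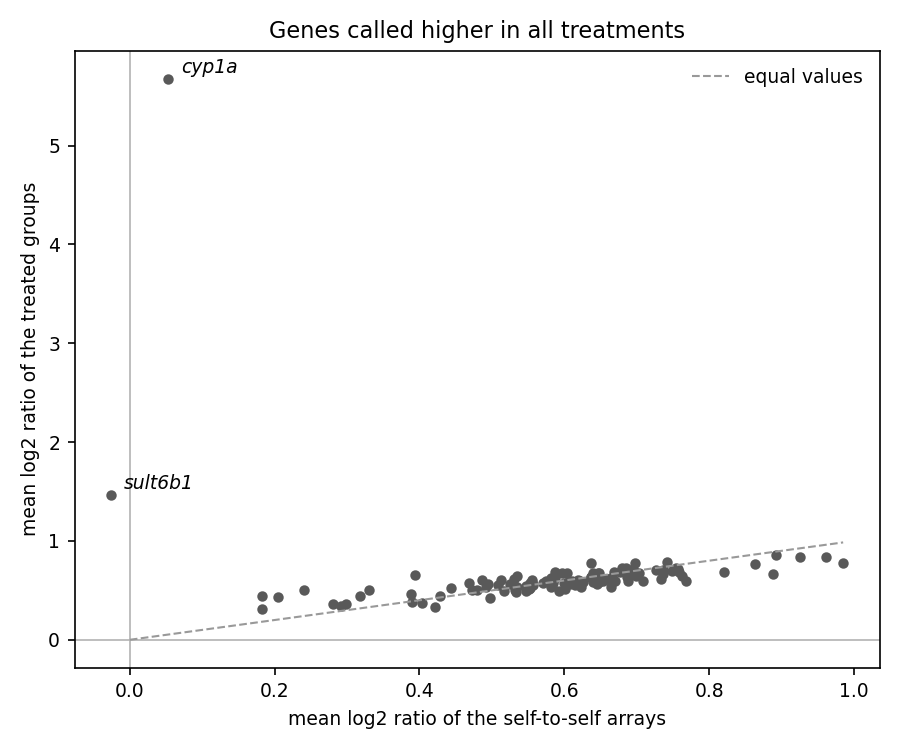
Mean log2 ratio over the 4 treated groups (vertical) against the mean log2 ratio on the 2 self-to-self arrays (horizontal) for the 117 genes called higher in all groups, with a dashed line where both are equal. cyp1a and sult6b1 stand above the line with self-to-self means under 0.1, and the median gene lies at 0.608 and 0.595.

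b-Naphthoflavone and benzo(a)pyrene at 2 dpf were compared directly to ask where their responses differ, at doses of 38.5 and 33.2 µg/L. cyp1a was higher under b-naphthoflavone by 2.02 on the log2 scale (95 percent interval 1.13 to 2.91, n = 3 in each group, adjusted p = 0.0251), with 0.59 within scan day 2 and 2.79 within scan day 3. Values within a day or slide rest on 1 or 2 arrays of each group, and those of b-naphthoflavone within day 2 on replicate 2 alone. That array had 5 spots with a very high local background. cyp1a was called in 13 of 22 alternatives, with an adjusted p up to 0.161. The difference was 1.21 for cyp1b1 (0.69 to 1.72, with 0.48 and 1.87 within the days), 1.35 for gstp1.2 (0.74 to 1.96), 0.63 for sox9b (0.34 to 0.91) and 2.22 for desi1a (1.82 to 2.63, with 1.8 and 2.6 within the days). cyp1c1 gave 1.06 (0.44 to 1.68, adjusted p = 0.0606, with 0.0262 and 1.9 within the days), and sult6b1 (0.42, -0.07 to 0.91) and nqo1 (-0.76, -1.60 to 0.08) were not called, with intervals that include 0. The lipid carrier apoa2 was 29.8-fold lower under b-naphthoflavone (log2 -4.90, -6.94 to -2.86, with -5.41 and -4.61 within the days), and apobb.1 (-4.19), apoa4b.1 (-4.13), apoa4b.2 (-4.04) and the protease ctslb (-3.90), a hatching gland marker, followed. Part of these sizes lies in the control channel. Against the other 2 compounds apoa2 differed by -2.86 in the treated and 2.02 in the control channel, and ctslb by -1.24 and 2.27.

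For the AhR battery, 4 of 15 were higher under b-naphthoflavone than under benzo(a)pyrene, 0 lower, and 7 adjusted over the list alone (list median 0.42, adjusted p = 0.00202, adjusted p = 0.499 with an estimated correlation). The list's median was 0.298 with scan day as a block, -0.079 within day 2 and 0.583 within day 3. Liver was lower in 17 of 40, 29 adjusted over the list alone (median -0.71, adjusted p = 1.6e-11), at -0.603 and -0.808 within the days. Lower lists also included lens with 5 of 40, 27 adjusted over the list alone (median -0.63, adjusted p = 1.05e-11, -0.505 and -0.748 within the days), and epidermis with 8 of 39, 26 adjusted over the list alone (median -0.69, adjusted p = 3.31e-10, -0.69 and -0.36 within the days). Intestine was lower in 8 of 33, 13 adjusted over the list alone (adjusted p = 1.58e-05), other cytochromes P450 in 4 of 29, 11 adjusted over the list alone (adjusted p = 0.00741). The circadian list was higher in 2 of 29, 4 adjusted over the list alone (adjusted p = 0.00713), with cry5 at 1.08. The photoreceptor list was lower (adjusted p = 0.00741) although its only called gene, gnb1b (0.73), was higher. The 16 called lists all gave an adjusted p of at least 0.499 with an estimated correlation. With scan day as a block the immune (adjusted p = 0.0736), photoreceptor (adjusted p = 0.203) and yolk and estrogen (adjusted p = 0.0524) lists lost their call. With median centring the yolk and estrogen list turned from a median of -0.225 to 0.327 relative to all genes and the ribosomal list turned from a median of 0.0972 to -0.397 relative to all genes. With limma 727 genes differed, 202 higher and 525 lower under b-naphthoflavone, 89 with scan day as a block and 139 with median centring. Leaving out 1 array gave 129 without b-naphthoflavone replicate 1 and 1135 without its replicate 3, and 27, 365 and 69 without benzo(a)pyrene replicates 1, 2 and 3. The share that was higher was 44.3 percent with the processed signals and 4.32 percent with median centring, against 27.8 percent.

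Benzo(k)fluoranthene and benzo(a)pyrene are isomers, and their doses here were 12.7 and 33.2 µg/L. cyp1a was 26.1-fold higher under benzo(k)fluoranthene (log2 4.71, 95 percent interval 3.82 to 5.60, n = 3 in each group, adjusted p = 0.000453), with 4.75 within slide 4 and 4.62 within slide 5. The differences were 3.51 for cyp1c1 (2.89 to 4.13), 3.13 for ahrra (2.52 to 3.74), 2.65 for cyp1b1 (2.14 to 3.17) and 2.44 for cyp1c2 (1.92 to 2.96), and within the slides they ran from 2.41 for cyp1c2 to 3.74 for cyp1c1. cyp1a, cyp1c1, ahrra and cyp1c2 kept their call in 22 of 22 alternatives and cyp1b1 in 21, with an adjusted p = 0.0516 in the other. sult6b1 gave 1.37 (0.89 to 1.86, adjusted p = 0.117), which was not called although its interval leaves out 0. ahrrb was not called either (adjusted p = 0.117), and its probe was not above background in either channel under benzo(a)pyrene. Also not called were nqo1 (-0.04, -0.88 to 0.80, with 0.53 and -1.18 within the slides), sox9b (0.08, -0.21 to 0.36) and cyp1d1 (0.02, -0.18 to 0.22). With limma 6 genes differed, all higher under benzo(k)fluoranthene: the 5 genes above and 1 known only by its accession (log2 1.61, SE 0.154, adjusted p = 0.000711), chosen after its value was seen. At an unadjusted p under 0.05 there were 423, and 11 were called without benzo(k)fluoranthene replicate 3.

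The AhR battery differed as a list between the isomers, with 5 of 15 higher under benzo(k)fluoranthene and 9 adjusted over the list alone (median 0.64, adjusted p = 4.05e-34, adjusted p = 0.0118 with an estimated correlation), at 0.929 within slide 4 and 0.526 within slide 5. The liver list was not called (median -0.0315, adjusted p = 0.926), and its array medians differed between the slides: 0.863 and 0.898 under benzo(k)fluoranthene against 0.686 and 0.259 under benzo(a)pyrene on slide 4, and -0.0165 against 0.654 on slide 5. Another 8 lists were called with 0 genes each, among them ribosomal proteins (0.145, adjusted p = 6.23e-09), lens (-0.179, adjusted p = 5.66e-07) and epidermis (-0.203, adjusted p = 7.17e-08), and these 3 each gave an adjusted p = 0.764 with an estimated correlation. Within slides 4 and 5 they had medians of -0.099 and 0.597, -0.0016 and -0.674, and -0.0116 and -0.488.

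b-Naphthoflavone was set against benzo(k)fluoranthene at 2 dpf, at doses of 38.5 and 12.7 µg/L. cyp1a was lower under b-naphthoflavone by 2.69 on the log2 scale (difference -2.69, 95 percent interval -3.58 to -1.80, n = 3 in each group), with -4.16 within scan day 2 and -1.83 within day 3, and was called in 20 of 22 alternatives. Differences of -2.45 for cyp1c1 (-3.07 to -1.82, with -3.36 and -1.85 within the days), -2.30 for ahrra, -1.74 for cyp1c2, -1.45 for cyp1b1 and -0.95 for sult6b1 (-1.72 and -0.218 within the days) went the same way, and sox9b was higher by 0.55. Of 22 alternatives cyp1b1 was called in 18, sox9b in 13 and sult6b1 in 10 (adjusted p up to 0.435). desi1a (4.3-fold, with log2 differences of 1.74 and 2.35 within the days), mapk3 (1.58) and rab42a (1.23) were higher under b-naphthoflavone. apoa2 was lower by 4.88 (difference -4.88, with -6.92 and -1.52 within the days), apobb.1 was at -3.94 (-6.24 and -0.356 within the days) and the stress-responsive gene sesn3 at -1.18 (-1.33 and -0.735).

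Of the AhR battery 7 of 15 were lower and 1 higher under b-naphthoflavone than under benzo(k)fluoranthene, 11 adjusted over the list alone (median -0.72, adjusted p = 1.79e-05, adjusted p = 0.447 with an estimated correlation), at -1.17 and -0.433 within the days. Liver genes were lower in 18 of 40, 29 adjusted over the list alone (median -0.82, adjusted p = 6.23e-11, adjusted p = 0.447 with an estimated correlation), at -0.937 and -0.198 within the days. Immediate early genes were lower in 5 of 25, 11 adjusted over the list alone (adjusted p = 0.00583, adjusted p = 0.447 with an estimated correlation). Genes of DNA damage were lower in 3 of 31, 11 adjusted over the list alone (adjusted p = 0.0243, adjusted p = 0.485 with an estimated correlation). The neuron list was higher (adjusted p = 0.0112, adjusted p = 0.614 with an estimated correlation), at 0.361 within day 2 and -0.0724 within day 3, although its only called gene, glula (-0.87), was lower. Within day 3, which held benzo(k)fluoranthene replicate 3, the shift of red blood cells was 0.157 against -1.01 in day 2, that of heart muscle 0.24 against -0.671 and that of the epidermis 0.115 against -0.657. With median centring the neuron list turned from 0.146 to -0.181 relative to all genes and heat shock from 0.181 to -0.143, and other cytochromes P450 turned from -0.218 to 0.138. With limma 763 genes differed, 234 higher and 529 lower under b-naphthoflavone, 89 with scan day as a block, 346 with median centring and 5 with only the arrays of the groups compared. Leaving out benzo(k)fluoranthene replicates 1, 2 and 3 gave 72, 103 and 2753, and leaving out b-naphthoflavone replicates 1 and 3 gave 146 and 1166. The higher share was 44.1 percent with the processed signals and 7.51 percent with median centring, against 30.7 percent.

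**Figure D4:**
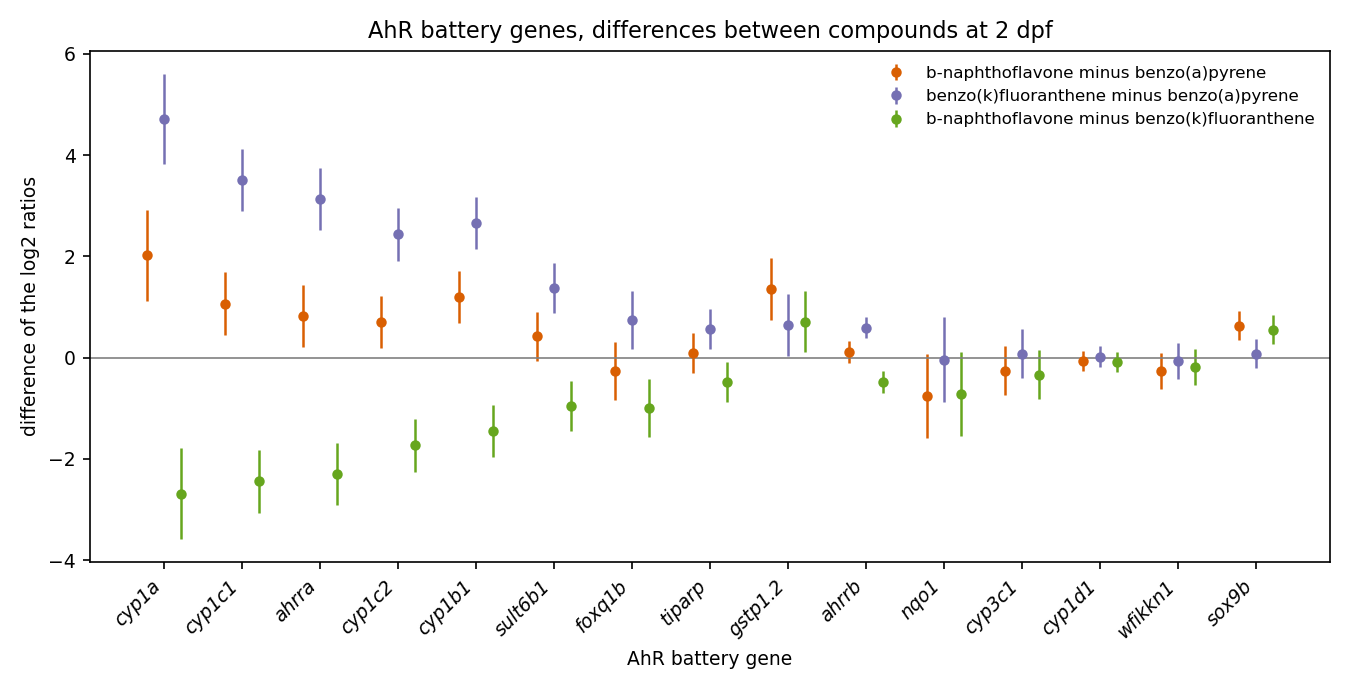
Difference in log2 ratio between pairs of compounds at 2 dpf for each AhR battery gene, as points with bars for the 95 percent interval. cyp1a differs by 4.71 between benzo(k)fluoranthene and benzo(a)pyrene, 2.02 between b-naphthoflavone and benzo(a)pyrene and -2.69 between b-naphthoflavone and benzo(k)fluoranthene, at doses that were not equal.

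A set of 120 genes, 77 with a symbol, was chosen after the data had been seen: those called at least 2-fold lower under b-naphthoflavone than under benzo(a)pyrene and than under benzo(k)fluoranthene at 2 dpf. That it is lower under b-naphthoflavone follows from this choice. It held 7 of 11 yolk syncytial layer markers, 1 of 5 hatching gland markers, 16 of 40 liver genes and 6 of 33 intestine genes. Its median log2 ratio was -1.23, -0.988 and -0.565 on the b-naphthoflavone arrays, 1.26, 0.444 and 0.974 on the benzo(a)pyrene arrays and 1.25, 1.36 and 0.0163 on the benzo(k)fluoranthene arrays, against -0.0837 on the self-to-self array of that stage. apoa2, apobb.1 and apoa4b.2 belong to this set, and replicates of 1 treatment differed by up to 1.34 in it. In the control channel its median lay between 10.18 and 10.22 on the b-naphthoflavone arrays and between 9.34 and 9.42 on those of the other 2 compounds.

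**Figure D5:**
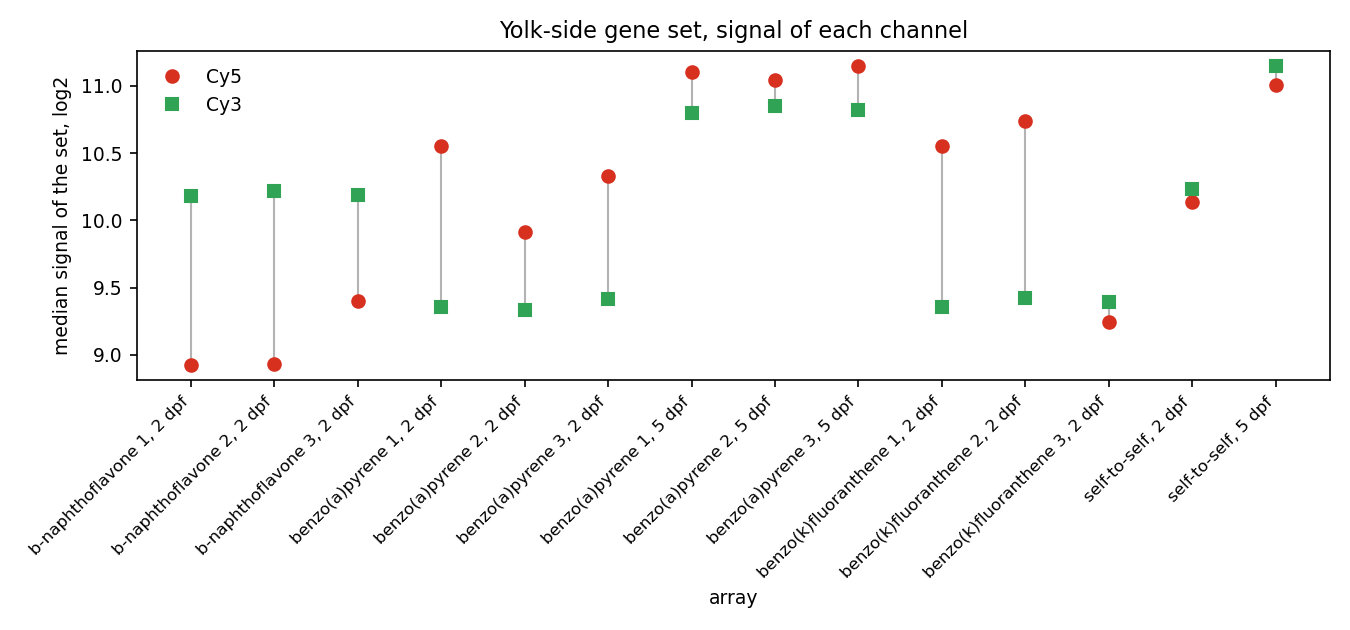
Median log2 signal of the 120 genes of the yolk-side set in the treated (Cy5) and control (Cy3) channels, with 1 pair of points per array. The treated channel runs from 8.93 to 9.40 under b-naphthoflavone and from 9.91 to 10.55 under benzo(a)pyrene at 2 dpf. Under benzo(k)fluoranthene it is 10.55, 10.74 and, on replicate 3, 9.24, and the control channel lies between 10.18 and 10.22 for b-naphthoflavone.

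Benzo(a)pyrene at 5 dpf was set against benzo(a)pyrene at 2 dpf, where stage, dose and exposure time differ together. cyp1b1 was 19.1-fold higher at 5 dpf (log2 4.26, 95 percent interval 3.74 to 4.77, n = 3 in each group, adjusted p = 1.58e-06), ahrra 17-fold, cyp1c1 11.1-fold and cyp1a 7.3-fold (log2 2.87, 1.97 to 3.76), which lost its call in 1 of 20 alternatives (adjusted p = 0.0626). ccl27a (2.45), socs3a (2.20) and klf2a (2.03) were higher. hamp (-2.33) and hmox1a (-1.76) were lower at 5 dpf. he1.2 and zgc:174855 were called lower too, but their signals lay near background at 5 dpf, so no size is given. All arrays of 5 dpf lay on 1 slide of 1 scan day with no array of 2 dpf, so slide and group cannot be told apart, and with slide as a random block limma called 293 genes.

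Of 20 lists called between the stages, 8 held with an estimated correlation. The AhR battery was higher in 7 of 15, 10 adjusted over the list alone (adjusted p = 8.94e-12, adjusted p = 0.0422 with an estimated correlation). Immediate early genes were higher in 9 of 25, 15 adjusted over the list alone (adjusted p = 1.56e-18, adjusted p = 0.0077 with an estimated correlation). The circadian list was higher in 7 of 29, such as cry5 (1.83), tefa (1.25) and per1b (0.94), 12 adjusted over the list alone (adjusted p = 1.03e-08, adjusted p = 0.00932 with an estimated correlation). Glucocorticoid genes were higher in 6 of 20, such as klf9 (1.77) and fkbp5 (1.61), 6 adjusted over the list alone (adjusted p = 5.92e-06, adjusted p = 0.00932 with an estimated correlation). Exocrine pancreas was higher in 14 of 25, such as amy2al2 (1.72), 23 adjusted over the list alone (adjusted p = 8.66e-28). Genes of DNA damage were higher in 5 of 31, such as gadd45ab (1.21), 9 adjusted over the list alone (adjusted p = 2.29e-06). Pigment cells were lower in 2 of 24, 4 adjusted over the list alone (adjusted p = 0.000785), and the retinoid list was in 1 of 22, 2 adjusted over the list alone (adjusted p = 0.000833). These last 4 gave an adjusted p = 0.0422 with an estimated correlation, and with median centring the DNA damage list was not called (adjusted p = 0.198). Immune genes were higher in 9 of 40, such as nfkbiab (1.54), 12 adjusted over the list alone (adjusted p = 8.47e-09, adjusted p = 0.0674 with an estimated correlation). Photoreceptor genes were lower in 5 of 44, 18 adjusted over the list alone (adjusted p = 2.63e-12, adjusted p = 0.181 with an estimated correlation). The liver list was lower, with tat (1.11) and pah (0.70) higher and hamp lower (list adjusted p = 0.00462, adjusted p = 0.676 with an estimated correlation). With limma 470 genes differed, 414 higher and 56 lower at 5 dpf, and 126 by at least 2-fold. The count was 206 without replicate 1 of 5 dpf and 276 without its replicate 2, and 253, 241 and 251 without replicates 1, 2 and 3 of 2 dpf.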

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

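The tests of the yolk-side set, of a dye effect by direction of the call and of an array of another treatment were chosen after the result was seen. Differences between treatments that passed a test of the difference itself numbered 727 genes for b-naphthoflavone against benzo(a)pyrene, 6 for benzo(k)fluoranthene against benzo(a)pyrene, 763 for b-naphthoflavone against benzo(k)fluoranthene and 470 for benzo(a)pyrene at 5 dpf against 2 dpf. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In all 4 comparisons every split but the real one gave 0 calls. At an unadjusted p under 0.05 the highest other splits gave 1524, 1792, 4478 and 985 genes, against 4877, 423, 5199 and 2611 for the real splits. For benzo(k)fluoranthene against benzo(a)pyrene the highest other split gave more than the real one, which points to a structure of the samples that does not follow the compounds. Compound and dose changed together in the 3 differences at 2 dpf and stay open and untested. So does slide for the differences of b-naphthoflavone, whose arrays lay alone on slides 1, 2 and 3. With scan day as a block each difference had 89 calls, but that fit cannot use b-naphthoflavone replicate 1, alone on its day. Leaving that array out gave 129 and 146, so the drop need not be a day effect. For benzo(a)pyrene at 5 against 2 dpf stage, dose, exposure time, slide and scan day changed together and stay open.

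A signal outside the comparisons was seen in the control channels. Between the DMSO channels of b-naphthoflavone and benzo(a)pyrene 191 genes differed at least 2-fold, 138 higher and 53 lower in the former, and between those of b-naphthoflavone and benzo(k)fluoranthene 131 did. The channels of benzo(k)fluoranthene and benzo(a)pyrene differed in 49 genes, and those of b-naphthoflavone and the self-to-self array of 2 dpf in 37. These differences were counted without a test, and whether arrays shared a control pool is not given in the sources used here.

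That the yolk-side set is lower under b-naphthoflavone follows from its choice. The self-to-self array of 2 dpf gave -0.0837, against a dye effect. The control channel of the set was higher by a median of 0.822 on the b-naphthoflavone arrays and the treated channel lower (median difference -1.06), but genes chosen by their ratio are pushed apart in both channels. The set's median in the treated channel had an SD of 0.557 over the 6 arrays of the other compounds, and benzo(k)fluoranthene replicate 3 (9.24) lay within the range of b-naphthoflavone (8.93 to 9.40), so differing control pools may carry all or part of the difference. These cannot be told apart from embryos at another stage, with 78.3 percent of the set higher in the control pools of 5 dpf than of 2 dpf, or from yolk-side tissue in differing amounts, as the range of 1.34 between replicates of benzo(k)fluoranthene is what prompted that test, and an effect of the compounds stays open and untested.

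A dye effect specific to genes was weighed for the calls against DMSO, since no dye was swapped. As a percent of the calls' median size, the median self-to-self ratio in their direction was 15.2 for b-naphthoflavone and 11.5 for benzo(a)pyrene at 5 dpf. It was 40.1 and 26.7 for benzo(a)pyrene and benzo(k)fluoranthene at 2 dpf. It averages 2 arrays that did not correlate (-0.0199), so it cannot decide for a whole group. By direction it was 10.8 for the lower calls of b-naphthoflavone and 10.6 for the higher calls at 5 dpf. Both stayed under 25 on each array, which argues against a dye effect for most of these calls. The effect stays open for the higher calls of b-naphthoflavone (25.4, 38.1 on the array of 2 dpf) and the lower calls at 5 dpf (12.9, but 30.9 on 1 array). So it does for the higher and lower calls of benzo(a)pyrene (43.7 and 27) and benzo(k)fluoranthene (23.8 and 30.3) at 2 dpf. The 117 genes higher in all 4 groups may be mostly of this kind apart from cyp1a and sult6b1, as their self-to-self median of 0.608 was as large as their ratio of 0.595.

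Replicate 3 of benzo(k)fluoranthene stood apart from replicates 1 and 2, with a departure of -1.34 in the yolk-side set. A slide effect would move replicate 3 of benzo(a)pyrene, on the same slide, alike, but the departures correlated at -0.328 across genes. The 11 AhR battery genes called without replicate 3 departed on it by a median of -0.16, from -1.38 to 0.216, against medians from -1.76 to -1.08 for the arrays of b-naphthoflavone and benzo(a)pyrene at 2 dpf, which argues against an array of these 2. Over 719 genes at least 4-fold apart between the control channels of 5 and 2 dpf its treated channel lay at -0.0635, with 0 for the other arrays of 2 dpf (-0.0563 to 0.0498) and 1 for those of 5 dpf (0.979 to 1.01), against a sample of 5 dpf. The amount of yolk-side tissue and a difference between the embryos stay open and untested, and groups of 3 arrays were not tested for single arrays far from the rest.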

How the results depend on the processing

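Leaving out non-uniform spots before background correction, leaving out both doubted arrays and using the treated channel alone were chosen after seeing the data. Named genes gave 466 results with 8971 alternative values, of which 6857 kept their side of the threshold, not always their sign if uncalled. Of the rest 2024 kept direction but lost the call, 60 gained one, 12 moved untested and 18 reversed. cyp1a was called in every alternative run for b-naphthoflavone (2.97 to 6.01), benzo(k)fluoranthene (5.26 to 8.63) and benzo(a)pyrene at 5 dpf (4.66 to 6.32), and in 17 of 18 for benzo(a)pyrene at 2 dpf (1.72 to 3.73). Counts below are of called genes, in the order b-naphthoflavone, benzo(a)pyrene at 2 dpf, benzo(k)fluoranthene and benzo(a)pyrene at 5 dpf against DMSO, then the differences, and counts not named stayed within 1.5 times the value reported. The cause was not tested except where the construction shows it.

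No background correction gave 3484 for b-naphthoflavone, 2415 for b-naphthoflavone minus benzo(a)pyrene and 2250 for b-naphthoflavone minus benzo(k)fluoranthene. The series table gave 3272, 2251 and 2004 for these 3, and leaving out marked spots before background correction 3195, 2102 and 1998, where the SD of the ratios of b-naphthoflavone replicate 2 was 0.363 in place of 0.238. The processed signals gave 3890 for b-naphthoflavone, 1509 for benzo(a)pyrene at 5 dpf, 2448 and 2195 for the differences of b-naphthoflavone, and 153 for benzo(a)pyrene at 5 minus 2 dpf. Median centring gave 99, 6640, 11605 and 564 against DMSO, and 139 and 346 for the differences of b-naphthoflavone. It moves the median of all genes by 0.234 for benzo(a)pyrene at 2 dpf and 0.28 for benzo(k)fluoranthene, so many of those calls are the shift itself. Aquantile scaling after loess left every ratio as it was by construction. With probes well above background in both channels on all treated arrays, which left 15429 genes, benzo(a)pyrene had 2002 at 5 dpf and 179 for 5 minus 2 dpf. The mean of the probes of a gene gave 1009 for b-naphthoflavone, 157 for benzo(a)pyrene at 2 dpf, and 396 and 478 for the differences of b-naphthoflavone.

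Trend and robust options gave 2 for benzo(a)pyrene at 2 dpf and 867 for benzo(k)fluoranthene. With only the arrays of the groups compared the spread is no longer pooled: 6 for b-naphthoflavone, 2398 for benzo(a)pyrene at 2 dpf, 11 for benzo(k)fluoranthene, 5 for b-naphthoflavone minus benzo(k)fluoranthene and 831 for benzo(a)pyrene at 5 minus 2 dpf. Against the mean of the self-to-self arrays the counts were 29, 0, 8 and 470, where that mean of 2 arrays adds its own error. Replicate numbers did not pair the arrays, with a correlation over 0.1 in 6 of 18 same-numbered pairs (-0.536 to 0.612), and a replicate block gave 195 for benzo(a)pyrene at 2 dpf and 407 and 503 for the differences of b-naphthoflavone. Slide as a random block gave 161 for benzo(a)pyrene at 2 dpf, 780 for benzo(k)fluoranthene, 1787 for benzo(a)pyrene at 5 dpf, 393 and 408 for the differences of b-naphthoflavone and 293 for benzo(a)pyrene at 5 minus 2 dpf. Scan day as a fixed block, which cannot use b-naphthoflavone replicate 1, gave 89 for each of its differences. Without both doubted arrays the counts were 2738, 1133 and 3233 at 2 dpf, 1633 for b-naphthoflavone minus benzo(a)pyrene, 11 for benzo(k)fluoranthene minus benzo(a)pyrene and 2493 for b-naphthoflavone minus benzo(k)fluoranthene. The treated channel alone gave 280 and 251 for the differences of b-naphthoflavone. Asking for at least 2-fold left 91, 19, 70 and 169 against DMSO and 191, 189 and 126 for the differences of b-naphthoflavone and of the stages.

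With an estimated correlation between genes the called lists were 0, 0, 0 and 2 against DMSO, 0 for b-naphthoflavone minus benzo(a)pyrene, 1 for benzo(k)fluoranthene minus benzo(a)pyrene, 0 for b-naphthoflavone minus benzo(k)fluoranthene and 8 for the stages.

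Leaving out 1 array at a time leaves 2 in its group, and limma pools their spread with the other groups. The lowest and highest counts were 462 and 2105 for b-naphthoflavone, 1 and 2 for benzo(a)pyrene at 2 dpf, 239 and 3141 for benzo(k)fluoranthene, and 968 and 2181 for benzo(a)pyrene at 5 dpf. For the differences they were 27 and 1135 for b-naphthoflavone minus benzo(a)pyrene, 6 and 11 for benzo(k)fluoranthene minus benzo(a)pyrene, 72 and 2753 for b-naphthoflavone minus benzo(k)fluoranthene, and 206 and 468 for the stages. Called lists ranged from 10 to 18 for benzo(k)fluoranthene and from 8 to 18 for benzo(k)fluoranthene minus benzo(a)pyrene.

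Directions reversed with median centring for benzo(a)pyrene at 2 dpf in ahrrb (-0.465), cs (0.322), dicer1 (0.0226), mybphb (0.286) and qki2 (0.0149), and for benzo(k)fluoranthene in eno2 (0.11), nr1d2b (0.0257), slc6a1b (0.259), stxbp1a (0.135) and tnfb (-0.0275). They also reversed with it in nr1d2b (-0.0256) for b-naphthoflavone minus benzo(k)fluoranthene and prph2a (0.00234) for the stages. Relative to the shift of all genes given above, dicer1 and qki2 for benzo(a)pyrene and eno2, nr1d2b, slc6a1b and stxbp1a for benzo(k)fluoranthene stayed below other genes. Against the self-to-self arrays rps18 reversed for benzo(a)pyrene at 2 dpf (-0.0517), and with the mean of probes wfikkn1 for benzo(k)fluoranthene (0.727). With the treated channel alone cyp2ad3 (0.0332) reversed for b-naphthoflavone minus benzo(a)pyrene, and ccn1 (0.0205), ptgs2b (0.132) and socs3a (0.11) for b-naphthoflavone minus benzo(k)fluoranthene.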

Other observations

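This part gives values alone, with no test and no explanation. Of 21168 genes with a value on the self-to-self array of 2 dpf, 59 lay at least 2-fold from equal, 4 higher and 55 lower, and 95 percent of genes lay within 0.385 of 0 on the log2 scale. On the array of benzo(a)pyrene RNA at 5 dpf the count was 7 of 21274, 5 higher and 2 lower, with 95 percent of genes within 0.307. cyp1c1 was -0.0401 on the first and -0.115 on the second, although its signal there was 12.4 and 12.5 in the 2 channels, against 8.51 and 8.55 on the first. The covariance of the ratios of the self-to-self arrays across genes, which are not independent replicates, was -0.000639.

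The typical spread of a gene between replicates was larger in the treated than in the control channel for benzo(a)pyrene at 2 dpf (0.132 against 0.0792), benzo(k)fluoranthene (0.175 against 0.085) and benzo(a)pyrene at 5 dpf (0.121 against 0.0513). For b-naphthoflavone, whose arrays were on 3 slides, it was 0.167 against 0.184.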
